A study of Mus musculus with 30 samples.

How the data were processed

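Heart, liver and lung of untreated and drug-treated mice were profiled on Illumina mouse bead arrays, per the labels, from total RNA extracted with Trizol and RNeasy columns with DNase treatment and labelled with biotin. Groups were taken from the labels: untreated, doxorubicin at day 1 or 6 and etoposide at day 1 or 6 in each of 3 tissues, with 2 arrays per group and 30 in all. A probe's intensity on a linear scale, not normalized, was deposited in 1 table for heart and liver and in another for lung, per the file headers. Each intensity had a detection p-value beside it, deposited by the authors, per the file headers. In 5 cells of the deposited tables the detection p, the other kind of value used, lay below 0, and these were read as 0. The authors also deposited normalized values, taken to be on a log2 scale from their relation to the intensities: over bright probes (log2 intensity above 10) they followed the log2 intensity with slopes of 0.958 to 1.04. Their medians were 3.16 to 3.19 in heart, 3.12 to 3.18 in liver and 3.47 to 3.52 in lung, and whether lung was normalized apart is not given in the sources used here. The package lumi is named in the submitters' processing notes with no version, and its settings are not given in the sources used here. The scale and centring of the deposited log2 values are thus known only from this comparison. For 2 lung arrays, those of etoposide day 1, the replicate numbers of the unnormalized table and of the normalized values were exchanged (rank correlation 0.915 with the same number and 1 with the other), which alters no group. Of the per-sample columns, 6 in each of 2 tables (12 in all) belonged to no sample given here and were not used.

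Raw medians were 64.6 to 76.5 in heart, 64.1 to 75.5 in liver and 78.5 to 84.4 in lung. In R 4.3.3 with limma 3.58.1, intensities were background-corrected from the detection p, quantile-normalized and log2-transformed (neqc, offset 16), separately for each tissue, and over all 30 arrays for comparisons between tissues. Probes were kept where the detection p was under 0.05 on both arrays of at least 1 group of the tissue. Of 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 none, and 34807 symbols were updated through Entrez identifiers. A gene took the values of its brightest probe, which left 11197 genes in heart, 10470 in liver, 12135 in lung and 13133 over all arrays. Where a probe was not above background on either array of a group, only a bound on the fold is given. Genes with near-identical copies (globins, histones, Hspa1a and Hspa1b, serum amyloid genes) cannot be separated with certainty by such probes.

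Groups were compared with lmFit and eBayes over the 10 arrays of a tissue, whose 5 groups share 1 estimate of the spread (5 residual degrees of freedom), with two-sided tests and Benjamini-Hochberg adjusted p under 0.05. Each tissue had 8 contrasts: each drug and day against untreated, the drugs at each day, and the days of each drug. Differences between tissues were tested with a moderated F test of the interaction over 15 groups. A total of 37 gene lists fixed in advance was tested with camera (preset correlation 0.01, at least 5 measured members, adjusted over the lists of a contrast), with an estimated correlation and with the rotation test fry. Of the camera calls within tissues, 3 held with an estimated correlation: p53 targets in lung at day 1 of doxorubicin against untreated and against etoposide, and erythroid genes in liver at day 6 of doxorubicin against etoposide. Agreement of the drugs was set against 100 simulations of unchanged groups. The genes named were chosen by rule: for each drug and day up to 8 rises and 8 falls with the largest change among called genes whose arrays did not overlap, up to 4 members with the smallest p of each list called by camera, the targets Top2a and Top2b and the p53 pathway genes Trp53, Cdkn1a and Mdm2, and for other contrasts up to 5 each way. Members of counts of 5 or fewer and other genes outside the rule were chosen after their values were seen.

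The fit was tested on simulated data with 200 changed genes for doxorubicin day 1 against untreated. At a log2 change of 1 it recovered 61% of these in heart (11197), 79% in liver (10470) and 71% in lung (12135), and at 2, 96%, 100% and 96%. False calls were 5.99%, 4.79% and 1.76% of the calls. No array difference like the 852 probes was simulated. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were no background correction, median centring, the authors' deposited values, no filter, a filter of detection p under 0.01 on every array, the mean of a gene's probes, the replicate number as a block, 1 fit over all arrays, a variance trend, and each array left out in turn. With 1 array left in a group, that lone sample is assumed to vary like the other groups. Chosen after the data were seen were the set of 852 probes, its mean deviation as a covariate, the omission of the pair of heart arrays with airway transcripts, a block with the exchanged lung numbers, and the agreement of the drugs without the probe set.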

Results

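Transcript levels were measured on Illumina mouse bead arrays in heart, liver and lung of FVB nude mice, an athymic strain, at 10 weeks of age. The mice had received a single intravenous dose of doxorubicin (10 mg/kg), an anthracycline, or of etoposide (35 mg/kg), a topoisomerase II poison of another chemical class, or had been left untreated. Tissue was taken at day 1 or day 6, and the title of the series sets the question of how tissues differ in their response. Each of the 15 groups held 2 arrays, 30 in all. The series names 2 mice per treatment, and its labels do not say which tissues came from the same mouse. Between 19018 and 20746 probes were detected per heart array, 17486 to 18927 per liver array and 22054 to 22884 per lung array. Correlations across genes between the arrays of a group lay between 0.935 (heart, doxorubicin day 6) and 0.993 (lung, doxorubicin day 6). Changes are log2 differences ± SE from limma with n = 2 arrays per group, and the number of arrays limits their precision. A call is a Benjamini-Hochberg adjusted p under 0.05 over all genes of the tissue.

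Several arrays carried transcripts of other tissues. Scgb1a1, a secretory protein of airway club cells, read 14.2 and 14.4 (log2) in replicate 2 of untreated heart and replicate 2 of heart at etoposide day 6, against 4.41 to 6.39 in the other 8 heart arrays. Myl7 and Sln, which mark the atria, ranged over the heart arrays from 4.48 to 14.7 and from 4.37 to 14.4, and both were high in the pair of doxorubicin day 6 arrays (14.1 to 14.7) and low in untreated replicate 1 (4.53 and 4.52). Apoa1, an apolipoprotein made by hepatocytes, ranged from 4.72 to 12.9 in heart, and the mean of 21 hepatocyte genes was 5.81 in replicate 1 and 11.1 in replicate 2 of heart at doxorubicin day 6. In lung the same genes averaged 8.88 in replicate 2 of etoposide day 1 and 5.72 to 6.63 in the other arrays. A further set of 852 probes was at least 1 log2 unit brighter in replicate 1 than in replicate 2 of heart at etoposide day 6, and this set was chosen after its values were seen. Its mean deviation was -0.72 and -0.80 in the untreated liver arrays, -0.85 and -0.80 in heart at doxorubicin day 1 and -0.86 in replicate 2 of heart at etoposide day 6, against -0.14 to 0.64 in all other heart and liver arrays. Counts for liver are therefore given with and without these probes, though others outside the set followed it too.

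**Figure D1:**
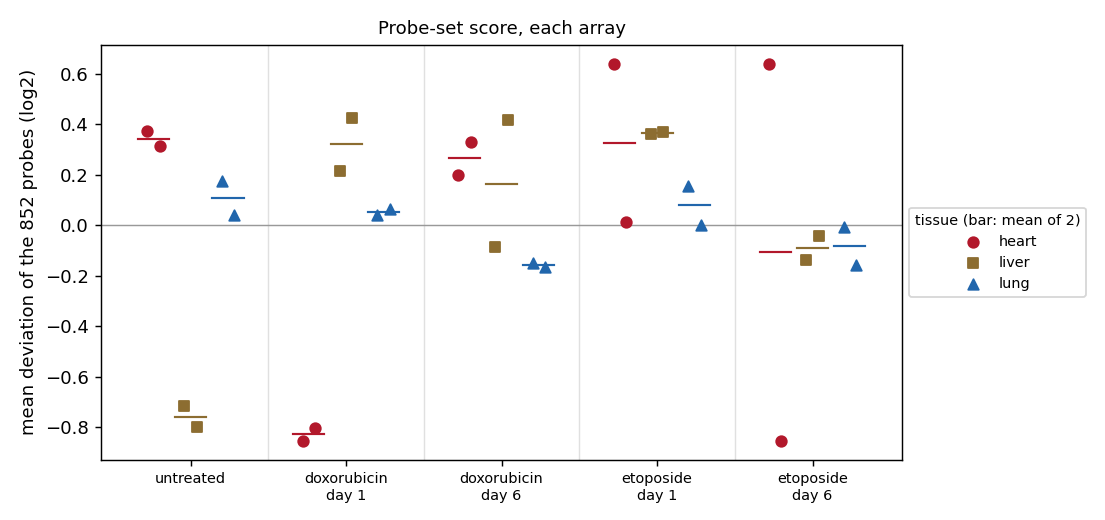
Mean deviation (log2, vertical) of the 852 probes on each array by condition (horizontal), with points for arrays of heart, liver and lung and a bar at the mean of the 2 arrays of a group. The untreated liver arrays lie at -0.72 and -0.80, and the heart arrays of doxorubicin day 1 at -0.85 and -0.80.

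Topoisomerase II, the target of both drugs, is encoded by Top2a, expressed in dividing cells, and Top2b, expressed in resting cells too. In untreated mice Top2a read 6.23 ± 1.01 in lung (mean log2 signal ± SD, n = 2), was detected in 1 of 2 untreated liver arrays and in 0 of 2 untreated heart arrays. It was at least 2.24-fold higher in lung than in heart (limma adjusted p = 0.0330), while lung and liver differed by 1.22 ± 0.58 (adjusted p = 0.0965). Such bounds set the brighter group against the lowest detected signal of each array where a probe was not above background in the other group. Top2b read 8.21 ± 0.04 in heart, 7.99 ± 0.23 in lung and 6.53 ± 0.02 in liver. Liver differed from heart by -1.69 ± 0.36 (limma adjusted p = 7.65e-04), and lung exceeded liver by 1.47 ± 0.36 (adjusted p = 0.0021). The Top2b probe belongs to the 852 probes on which the untreated liver arrays were low, and lung came from a table of its own and was normalized together with the others here.

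In heart at day 1 after doxorubicin, Srxn1, which encodes the antioxidant enzyme sulfiredoxin, rose by 2.35 ± 0.13 (limma adjusted p = 0.0014). H2ac6, a replication-dependent histone gene with close copies, rose at least 3.33-fold (adjusted p = 0.0146), and Ces1c, a carboxylesterase gene, was at least 11.8-fold lower (adjusted p = 2.34e-04). These were the 3 genes changed of 11197 (2 higher and 1 lower; 1735 at unadjusted p under 0.05). Of 28 interferon-stimulated genes, 0 rose and 0 fell over all genes (19 at unadjusted p under 0.05), and 18 rose and 0 fell adjusted over the list alone. Their median was 1.13 (camera adjusted p = 1.32e-12, or adjusted p = 0.235 with an estimated correlation). Ifit3 read 2.55 ± 0.34, Usp18, a protease of the interferon response, 2.12 ± 0.29 and the ubiquitin-like modifier gene Isg15 2.07 ± 0.26. Of 30 targets of p53, the transcription factor activated by DNA damage, 0 rose and 0 fell over all genes (15 at unadjusted p under 0.05), and 13 rose and 1 fell adjusted over the list alone. Their median was 0.53 (camera adjusted p = 3.08e-07, or adjusted p = 0.104 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, read 1.89 ± 0.25, Ephx1, an epoxide hydrolase gene, 1.49 ± 0.22 and Mdm2, the ubiquitin ligase gene of p53, 0.94 ± 0.12. Of 25 histone genes, whose copies are too alike to be told apart with certainty, 0 rose and 0 fell over all genes (12 at unadjusted p under 0.05), and 8 rose and 0 fell adjusted over the list alone. Their median was 0.42 (camera adjusted p = 5.30e-04, or adjusted p = 0.571 with an estimated correlation). Collagen gene Col3a1 read -2.29 ± 0.35 on its brightest probe and -0.51 on its other probes. Both arrays of this group were low on the 852 probes, and the count was 205 (48 higher, 157 lower) without either array of etoposide day 6. Without background correction 7 genes were higher and 1 lower, and with the authors' deposited values 1 and 0.

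At day 6 after doxorubicin, globin transcripts fell in heart. The haemoglobin gene Hba-a1 fell by 6.84 ± 0.32 (limma adjusted p = 3.69e-04), as did Hbb-bs (-7.47 ± 0.51), Hbb-bt (-7.34 ± 0.55) and Hbb-b2 (-6.80 ± 0.36), whose near-identical copies leave single genes uncertain. Alas2, the erythroid enzyme of haem synthesis, was at least 26.8-fold lower (adjusted p = 0.0363), Irs2, an adaptor of insulin signalling, rose by 2.36 ± 0.24 (adjusted p = 0.0319), and Ces1c was at least 12-fold lower. These were the 7 genes changed (824 at unadjusted p under 0.05). Of 11 erythroid genes, 0 rose and 4 fell over all genes, and 0 rose and 5 fell adjusted over the list alone. The median was -0.66 (camera adjusted p = 1.72e-10, or adjusted p = 0.107 with an estimated correlation). Of 17 immediate early genes, which answer acute stimuli, 0 rose and 0 fell over all genes (9 at unadjusted p under 0.05), and 5 rose and 0 fell adjusted over the list alone. Their median was 0.71 (camera adjusted p = 1.20e-08, or adjusted p = 0.431 with an estimated correlation). The mean of all 21 genes of the list on the platform was 8.0 and 8.93 in replicates 1 and 2, against 7.49 and 8.02 in the untreated arrays, so replicate 1 lay within their range. The stress-induced factor gene Atf3 read 3.27 ± 0.38. Of 14 heat shock genes, 0 rose and 0 fell over all genes (4 at unadjusted p under 0.05), and 4 rose and 0 fell adjusted over the list alone. Their median was 0.11 (camera adjusted p = 0.0189, or adjusted p = 0.431 with an estimated correlation). Hspa1a, which has a near-identical neighbour, read 4.04 ± 0.54 on its brightest probe and 1.36 on its others. Hepatocyte genes, whose mean differed between the arrays of this group (5.81 and 11.1), had a median of -1.48 (camera adjusted p = 0.0041, or adjusted p = 0.743 with an estimated correlation), and both arrays were high in the atrial genes Myl7 and Sln. The count was 4 without untreated replicate 1 and 54 (42 higher, 12 lower) without the pair of arrays with airway transcripts. Against the 1 gene higher and 6 lower, 4 were higher and 5 lower without background correction, and 0 and 7 with the authors' deposited values. With probes detected on every array 5 were higher and 3 lower.

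**Figure D2:**
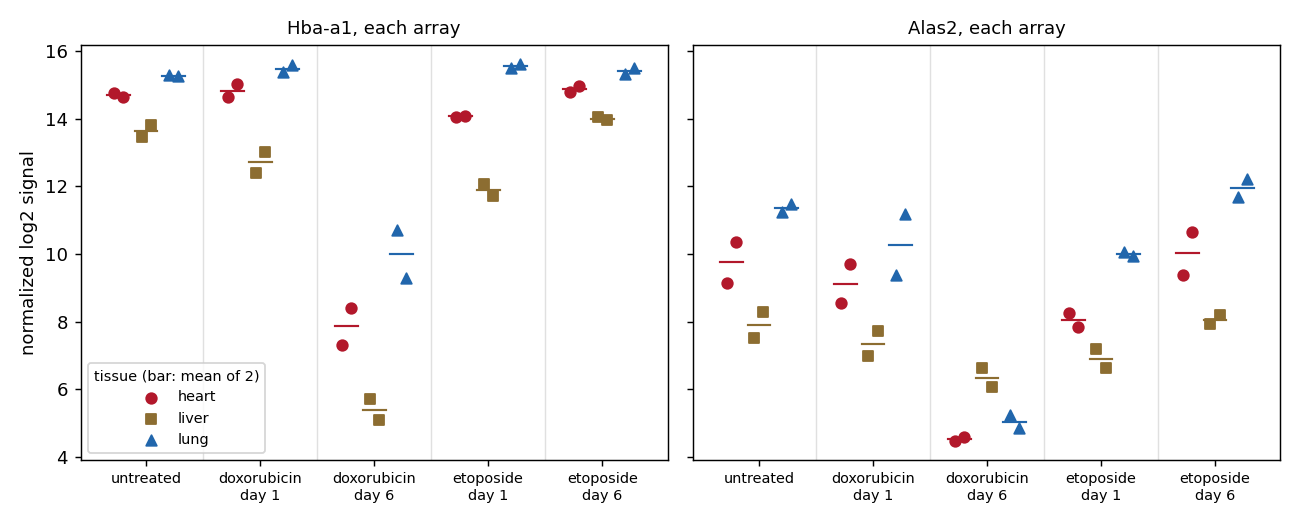
Normalized log2 signal (vertical) of Hba-a1 and Alas2 on each array by condition (horizontal), with points for arrays of heart, liver and lung, each tissue normalized on its own, and a bar at the mean of the 2 arrays of a group. At doxorubicin day 6 the mean of Hba-a1 differs from untreated by -6.84 in heart, -8.23 in liver and -5.26 in lung.

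From day 1 to day 6 of doxorubicin, the interferon-stimulated genes Usp18 (-2.58 ± 0.29), Ifit3 (-2.46 ± 0.34), Isg15 (-2.07 ± 0.26) and the histone genes H2bc6 (-1.11 ± 0.14) and H2bc12 (-1.07 ± 0.14) fell in heart. Atf3 rose by 2.85 ± 0.38 (limma adjusted p = 0.0419), the stress kinase gene Map3k6 by 1.69 ± 0.20 and Prkag2, a subunit of AMP-activated kinase, by 1.49 ± 0.15. The p53 target Aen was at least 1.66-fold lower and Hba-a1 fell by 6.97 ± 0.32. Psd3 (2.26 ± 0.28) and Hif3a (1.84 ± 0.22) rose on their brightest probes and read -0.04 and -0.24 on their others. Of the interferon-stimulated genes, 0 rose and 4 fell over all genes, and 0 rose and 18 fell adjusted over the list alone. Their median was -1.18 (camera adjusted p = 5.84e-13, or adjusted p = 0.227 with an estimated correlation). Of the histone genes, 0 rose and 2 fell over all genes, and 0 rose and 8 fell adjusted over the list alone. Their median was -0.34 (camera adjusted p = 5.60e-04, or adjusted p = 0.393 with an estimated correlation). In all 35 genes differed (10 higher, 25 lower at day 6; 2237 at unadjusted p under 0.05). Both arrays of day 1 were low on the 852 probes and those of day 6 were not, while both arrays of day 6 were high in atrial genes. Without those probes 52 genes differed, with their deviation as a covariate 1, with the replicate block 8 and with 1 fit over all 30 arrays 1047 (603 higher, 444 lower). The count was 4 and 2 without doxorubicin day 1 replicates 1 and 2, 12 and 8 without doxorubicin day 6 replicates 1 and 2, 6 without either array of etoposide day 1, 332 (245 higher, 87 lower) without either array of etoposide day 6 and 419 (321 higher, 98 lower) without the pair with airway transcripts, so the larger share was then higher at day 6.

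After etoposide, Ces1c was at least 11.8-fold lower in heart at day 1 (limma adjusted p = 1.62e-04) and at least 12.3-fold lower at day 6 (adjusted p = 1.87e-04), and it was the 1 gene changed on each day (388 and 694 at unadjusted p under 0.05). Of 11 erythroid genes at day 1, 0 rose and 0 fell over all genes (4 at unadjusted p under 0.05), and 0 rose and 1 fell adjusted over the list alone. Their median was -0.64 (camera adjusted p = 1.27e-05, or adjusted p = 0.382 with an estimated correlation). Hbb-b2 read -1.73 ± 0.36. At day 6, of 14 markers of T and natural killer cells, 0 rose and 0 fell over all genes (4 at unadjusted p under 0.05), and 2 rose and 0 fell adjusted over the list alone. Their median was 1.04 (camera adjusted p = 3.50e-05, or adjusted p = 0.701 with an estimated correlation). Eomes, a transcription factor of such cells, read 1.05 ± 0.25. Of 10 neutrophil genes, 0 rose and 0 fell over all genes (4 at unadjusted p under 0.05), and 3 rose and 0 fell adjusted over the list alone. Their median was 1.16 (camera adjusted p = 0.0018, or adjusted p = 0.701 with an estimated correlation). Retnlg read 2.12 ± 0.46 and the calgranulin gene S100a9 2.60 ± 0.78. Of 24 macrophage and monocyte genes, 0 rose and 0 fell over all genes (4 at unadjusted p under 0.05), and 0 rose and 1 fell adjusted over the list alone. Their median was 0.44 (camera adjusted p = 0.0013, or adjusted p = 0.727 with an estimated correlation). The chemokine receptor gene Cx3cr1 read -1.80 ± 0.30. The means of all neutrophil and of all macrophage and monocyte genes of the lists, dim ones included, in replicate 1 of this group (5.61 and 8.28) lay within the range of the untreated arrays (4.90 to 5.97 and 7.90 to 8.69). Replicate 2 of the day 6 group and of untreated heart carried the airway transcripts, and the day 6 count was 2 without untreated replicate 1. Day 6 and day 1 of etoposide differed in 0 genes by limma (840 at unadjusted p under 0.05). With median centring the median of all genes between these days was -0.108.

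Set against etoposide at day 1, doxorubicin gave higher Srxn1 (2.21 ± 0.13; limma adjusted p = 0.0042) and at least 3.39-fold higher H2ac6 (adjusted p = 0.0253) in heart, the 2 genes that differed (1330 at unadjusted p under 0.05). Of the p53 targets, 0 rose and 0 fell over all genes (19 at unadjusted p under 0.05), and 16 rose and 1 fell adjusted over the list alone. Their median was 0.52 (camera adjusted p = 5.89e-09, or adjusted p = 0.0642 with an estimated correlation). Cdkn1a read 1.86 ± 0.25. Of the interferon-stimulated genes, 0 rose and 0 fell over all genes (16 at unadjusted p under 0.05), and 16 rose and 0 fell adjusted over the list alone. Their median was 0.66 (camera adjusted p = 1.16e-10, or adjusted p = 0.243 with an estimated correlation). At day 6 the 5 genes that differed were lower after doxorubicin, namely Hba-a1 (-7.01 ± 0.32), Hbb-bs (-7.51 ± 0.51), Hbb-bt (-7.32 ± 0.55), Hbb-b2 (-6.61 ± 0.36) and Alas2, at least 32.3-fold (649 at unadjusted p under 0.05). Of the markers of T and natural killer cells, 0 rose and 0 fell over all genes (9 at unadjusted p under 0.05), and 0 rose and 9 fell adjusted over the list alone. Their median was -1.51 (camera adjusted p = 2.64e-08, or adjusted p = 0.253 with an estimated correlation). The day 1 count was 1 without doxorubicin day 1 replicate 1 or either array of doxorubicin day 6, 0 by limma without doxorubicin day 1 replicate 2 (659 at unadjusted p under 0.05), etoposide day 1 replicate 1 (442) or replicate 2 (1194), and 113 (27 higher, 86 lower) without either array of etoposide day 6. The day 6 count was 3 and 2 without etoposide day 6 replicates 1 and 2, and without the pair with airway transcripts the counts were 0 at day 1 by limma (1774 at unadjusted p under 0.05) and 2 at day 6.

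In liver at day 1 after doxorubicin, the p53 target Phlda3, an inhibitor of Akt, rose by 2.78 ± 0.22 (limma adjusted p = 0.0027), Cdkn1a by 2.77 ± 0.64 (adjusted p = 0.0331), the cyclin gene Ccng1 by 1.47 ± 0.15, Ephx1 by 1.62 ± 0.21 and Mdm2 by 0.74 ± 0.16. The glutathione transferase genes Gstm3 (3.35 ± 0.47) and Gstp1 (1.34 ± 0.14; other probes 2.40) and Gclc of glutathione synthesis (1.45 ± 0.19) rose, as did the chaperone genes Hsp90aa1 (2.08 ± 0.26), Hsph1 (1.27 ± 0.18) and Hspa8 (1.06 ± 0.15), the histone genes H4c9 (1.27 ± 0.16) and H4c8 (1.18 ± 0.19) and the acute phase gene Saa3 (3.64 ± 0.76), the last 3 having close copies. The noncoding RNA Hectd2os fell by 3.04 ± 0.39, as did the clock repressor gene Nr1d1 (-2.11 ± 0.35), the neurotrophin receptor gene Ntrk2 (-2.09 ± 0.41) and the integrated stress response genes Chac1 (-1.75 ± 0.42) and Trib3 (-1.72 ± 0.35). On leaving out each array in turn Cdkn1a ran from 1.69 to 3.85 (call kept on 6 of 10) and Chac1 from -2.43 to -1.08 (3 of 10). Probes of Gclc and Hspa8, outside the 852, followed their deviation (correlations 0.905 to 0.913 in heart and liver). In liver, but less or not in heart, so did Pck1 (0.90), Tat (0.88), Hsp90aa1 (0.87), Hsph1 (0.81), Hspa1b (0.80) and Saa3 (0.75). None is told apart from the set. Of 30 p53 targets, 12 rose and 0 fell over all genes, and 15 rose and 2 fell adjusted over the list alone. Their median was 0.48 (camera adjusted p = 2.25e-06, or adjusted p = 0.649 with an estimated correlation). Of 23 oxidative stress genes, 5 rose and 0 fell over all genes, and 9 rose and 1 fell adjusted over the list alone. Their median was 0.09 (camera adjusted p = 0.0029, or adjusted p = 0.734 with an estimated correlation). Of 14 heat shock genes, 8 rose and 0 fell over all genes, and 9 rose and 0 fell adjusted over the list alone. Their median was 0.65 (camera adjusted p = 2.25e-06, or adjusted p = 0.649 with an estimated correlation). Of 25 histone genes, 7 rose and 1 fell over all genes, and 9 rose and 2 fell adjusted over the list alone. Their median was 0.24 (camera adjusted p = 0.0011, or adjusted p = 0.649 with an estimated correlation).

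In all, 902 of 10470 liver genes changed at day 1 of doxorubicin (616 higher, 286 lower; 2677 at unadjusted p under 0.05), and with arrays centred on the median 88.9% rather than 68.3% of the changed genes were higher. Of these genes, 248 were read by the 852 probes on which the untreated liver arrays were low, Top2b (1.73 ± 0.21) among them. Without those probes, but with others that followed them, 501 genes changed. With the set's mean deviation as a covariate, which in liver nearly separates untreated from treated arrays, 0 passed in limma (609 at unadjusted p under 0.05). The count was 426 and 254 without untreated replicates 1 and 2 and 555 and 112 without doxorubicin day 1 replicates 1 and 2. Of 326 called genes with another detected probe, 141 (43.3%) changed the same way on one at unadjusted p under 0.05, and for the higher genes the median change was 0.14 on the other probes against 1.02 on their own.

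At day 6 after doxorubicin globin transcripts fell in liver as well. Hba-a1 fell by 8.23 ± 0.27 (limma adjusted p = 1.13e-06), as did Hbb-bs (-7.79 ± 0.25) and Hbb-bt (-7.95 ± 0.24), and Hbb-b2 was at least 20.9-fold lower. Cdkn1a rose by 3.28 ± 0.64 (adjusted p = 0.0218), Trp53inp1, a p53-induced gene, by 2.88 ± 0.45, Phlda3 by 2.38 ± 0.22 and the kinase gene Plk3 by 1.58 ± 0.23. Tyrosine aminotransferase Tat (2.76 ± 0.39), the gluconeogenic enzyme gene Pck1 (2.26 ± 0.31), the phosphatidate phosphatase gene Lpin1 (1.64 ± 0.24) and Angptl4, an inhibitor of lipoprotein lipase (1.44 ± 0.32), rose, while the sulfotransferase gene Sult2a6 (-2.66 ± 0.37), Hectd2os (-2.85 ± 0.39) and Nr1d1 (-1.98 ± 0.35) fell. Of 12 erythroid genes, 1 rose and 4 fell over all genes, and 1 rose and 4 fell adjusted over the list alone. Their median was -0.30 (camera adjusted p = 0.0059, or adjusted p = 0.486 with an estimated correlation). Of the p53 targets, 6 rose and 0 fell over all genes, and 6 rose and 0 fell adjusted over the list alone. Their median was 0.28 (camera adjusted p = 0.0023, or adjusted p = 0.995 with an estimated correlation). Of 19 glucocorticoid targets, 5 rose and 2 fell over all genes, and 7 rose and 2 fell adjusted over the list alone. Their median was 0.47 (camera adjusted p = 3.70e-04, or adjusted p = 0.995 with an estimated correlation). Of the heat shock genes, 3 rose and 0 fell over all genes, and 10 rose and 0 fell adjusted over the list alone. Their median was 0.60 (camera adjusted p = 5.54e-06, or adjusted p = 0.672 with an estimated correlation). Hspa1b read 3.55 ± 0.46 on its brightest probe and 0.48 on its others. In all 718 genes changed (481 higher, 237 lower; 2399 at unadjusted p under 0.05), 217 of them read by the 852 probes, and 361 changed without these and 3 with their deviation as a covariate. The count was 226 and 192 without untreated replicates 1 and 2 and 72 without doxorubicin day 6 replicate 2. With another detected probe, 126 of 258 called genes (48.8%) changed the same way on one at unadjusted p under 0.05.

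At day 1 after etoposide, globin transcripts fell in liver, Hba-a1 by a log2 change of -1.73 ± 0.27 (limma adjusted p = 0.0074), Hbb-bs of -1.70 ± 0.25, Hbb-bt of -1.75 ± 0.24 and Hbb-b2 of -1.45 ± 0.26. The transcription factor gene Zbtb16, a glucocorticoid target, fell by 1.87 ± 0.38 and Sult2a6 changed by -1.65 ± 0.37, between -2.29 and -1.01 on leaving out each array in turn (call kept on 1 of 10). Of the heat shock genes, 3 rose and 0 fell over all genes, and 7 rose and 0 fell adjusted over the list alone. Their median was 0.31 (camera adjusted p = 0.0117, or adjusted p = 0.973 with an estimated correlation). Hspa1b read 2.48 ± 0.46 and its other probes at 0.06. The p53 targets had a median of -0.02. Of 581 changed genes (527 higher, 54 lower; 1881 at unadjusted p under 0.05), 256 were read by the 852 probes, such as Prkar2a (2.65 ± 0.29), Rraga (2.38 ± 0.28) and Top2b (1.73 ± 0.21). Without these probes 204 genes changed, and with their deviation as a covariate 0 passed in limma (605 at unadjusted p under 0.05). The count was 177 without untreated replicate 2 and 207 and 123 without etoposide day 1 replicates 1 and 2. Of 203 called genes with another detected probe, 63 (31%) changed the same way on one at unadjusted p under 0.05, and for the higher genes the median change was 0.04 on the other probes against 1.10 on their own.

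At day 6 after etoposide, the replication licensing gene Cdc6 (1.32 ± 0.27; limma adjusted p = 0.0478), the kinetochore gene Spc25 (0.94 ± 0.16) and Stmn1, a microtubule regulator read by a probe of the 852 (2.92 ± 0.41), rose in liver. The platelet chemokine gene Pf4 (2.34 ± 0.47), the interleukin 1 antagonist gene Il1rn (2.51 ± 0.51) and the red cell anion exchanger gene Slc4a1 (1.91 ± 0.38) rose, as did Tat (2.21 ± 0.39) and Pck1 (1.91 ± 0.31). The lipoprotein receptor gene Vldlr fell by 2.44 ± 0.46, as did Nr1d1 (-2.26 ± 0.35), Sult2a6 (-2.18 ± 0.37) and the growth arrest gene Gadd45a (-1.68 ± 0.28). Of 35 cell cycle genes, 3 rose and 0 fell over all genes, and 25 rose and 0 fell adjusted over the list alone. Their median was 0.91 (camera adjusted p = 8.00e-16, or adjusted p = 0.691 with an estimated correlation). Of 24 macrophage and monocyte genes, 24 were higher in value and 0 rose and 0 fell over all genes (9 at unadjusted p under 0.05), and 0 rose and 0 fell adjusted over the list alone. Their median was 0.48 (camera adjusted p = 7.03e-07, or adjusted p = 0.9 with an estimated correlation). Of 18 neutrophil genes, 0 rose and 0 fell over all genes (5 at unadjusted p under 0.05), and 0 rose and 0 fell adjusted over the list alone. Their median was 1.06 (camera adjusted p = 7.15e-04, or adjusted p = 0.9 with an estimated correlation), and the mean of all genes of the list, dim ones included, in replicate 1 (7.67) lay within the range of the untreated arrays (5.69 to 8.26). Of the glucocorticoid targets, 3 rose and 2 fell over all genes, and 8 rose and 2 fell adjusted over the list alone. Their median was 0.53 (camera adjusted p = 4.66e-04, or adjusted p = 0.691 with an estimated correlation). In all 215 genes changed (127 higher, 88 lower; 2433 at unadjusted p under 0.05), 62 of them read by the 852 probes, and with median centring 73.0% rather than 59.1% were higher. The count was 56 without the 852 probes, 0 by limma with their deviation as a covariate (587 at unadjusted p under 0.05), 0 by limma without untreated replicate 1 (1555) or etoposide day 6 replicate 2 (1503), and 4 without etoposide day 6 replicate 1. It was 59 without untreated replicate 2, 92 without either array of doxorubicin day 1, 403 without either array of doxorubicin day 6 and 14 without either array of etoposide day 1. With another detected probe, 55 of 82 called genes (67.1%) changed the same way on one at unadjusted p under 0.05.

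Doxorubicin and etoposide differed in 3 liver genes at day 1, all higher after doxorubicin (919 at unadjusted p under 0.05): Phlda3 (2.20 ± 0.22; limma adjusted p = 0.0323), Gstp1 (1.36 ± 0.14) and Ccng1 (1.36 ± 0.15). Of the p53 targets, 2 rose and 0 fell over all genes, and 14 rose and 0 fell adjusted over the list alone. Their median was 0.58 (camera adjusted p = 6.96e-12, or adjusted p = 0.188 with an estimated correlation). At day 6 the 5 genes that differed (905 at unadjusted p under 0.05) were Hba-a1 (-8.60 ± 0.27; limma adjusted p = 7.70e-07), Hbb-bs (-8.13 ± 0.25), Hbb-bt (-8.27 ± 0.24), Hbb-b2, at least 34.3-fold lower, and Phlda3 (2.15 ± 0.22). Of the erythroid genes, 0 rose and 3 fell over all genes, and 0 rose and 5 fell adjusted over the list alone (camera adjusted p = 1.27e-09, or adjusted p = 0.0295 with an estimated correlation), and of the cell cycle genes, 0 rose and 0 fell over all genes (27 at unadjusted p under 0.05), and 1 rose and 19 fell adjusted over the list alone. Their median was -0.99 (camera adjusted p = 3.59e-18, or adjusted p = 0.554 with an estimated correlation). The day 1 count was 0 by limma without doxorubicin day 1 replicate 1 (948 at unadjusted p under 0.05) or 2 (639) or etoposide day 1 replicate 1 (690) or 2 (609), 6 without either array of doxorubicin day 6 and 1 without either array of etoposide day 6. The day 6 count was 25 without etoposide day 6 replicate 1. With all arrays, 1 gene was higher and 4 lower after doxorubicin at day 6, against 0 and 4 with the authors' deposited values. Without the 852 probes 4 genes differed at day 1 and 5 at day 6.

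From day 1 to day 6 of doxorubicin, Lpin1 (2.57 ± 0.24), Chac1 (2.56 ± 0.42), Zbtb16 (2.40 ± 0.38) and the endoplasmic reticulum stress gene Herpud1 (1.16 ± 0.18) rose in liver, while Gstp1 (-1.55 ± 0.14), H4c9 (-1.20 ± 0.16) and Hba-a1 (-7.30 ± 0.27) fell. In all 48 genes differed by limma (16 higher, 32 lower; 1716 at unadjusted p under 0.05), and with median centring, which shifted the median of all genes to -0.116, 12.3% rather than 33.3% were higher. For etoposide, Hba-a1 (2.10 ± 0.27), Hbb-b2 (2.17 ± 0.26), Hbb-bs (2.04 ± 0.25) and Zbtb16 (2.84 ± 0.38) rose, Slc4a1 was at least 5.14-fold higher and the plasma glycoprotein gene A1bg (-2.07 ± 0.32) fell. In all 51 genes differed (24 higher, 27 lower; 2150 at unadjusted p under 0.05). Of the cell cycle genes, 0 rose and 0 fell over all genes (25 at unadjusted p under 0.05), and 24 rose and 0 fell adjusted over the list alone. Their median was 1.04 (camera adjusted p = 2.32e-14, or adjusted p = 0.549 with an estimated correlation). The doxorubicin count was 11 and 4 without doxorubicin day 1 replicates 1 and 2, 6 and 5 without doxorubicin day 6 replicates 1 and 2, 14 without either array of etoposide day 1 and 12 without either of etoposide day 6. The etoposide count was 163 (101 higher, 62 lower) without either untreated array, 13 and 93 without either array of doxorubicin day 1 and of day 6, 0 by limma without etoposide day 1 replicate 1 (1814 at unadjusted p under 0.05) or 2 (1088) or etoposide day 6 replicate 2 (1441), and 93 (85 higher, 8 lower) without etoposide day 6 replicate 1. With the authors' deposited values 3 genes were higher and 14 lower at day 6 of doxorubicin. Without the 852 probes 57 genes differed between the days of doxorubicin and 46 between those of etoposide.

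In lung at day 1 after doxorubicin, Cdkn1a rose by 1.84 ± 0.19 (limma adjusted p = 0.0414), Zfp365, a zinc finger gene, by 1.96 ± 0.18 (other probes 0.98), and the carboxylesterase gene Ces2e at least 3.42-fold. These were the 3 genes changed of 12135 (749 at unadjusted p under 0.05). Of 30 p53 targets, 1 rose and 0 fell over all genes, and 15 rose and 0 fell adjusted over the list alone. Their median was 0.37 (camera adjusted p = 1.95e-15, or adjusted p = 0.0071 with an estimated correlation). Ccng1 read 1.69 ± 0.24, Phlda3 at 1.57 ± 0.18 and Ephx1 at 1.18 ± 0.14. Of 14 heat shock genes, 0 rose and 0 fell over all genes (5 at unadjusted p under 0.05), and 1 rose and 0 fell adjusted over the list alone. Their median was 0.32 (camera adjusted p = 2.23e-06, or adjusted p = 0.177 with an estimated correlation). The small chaperone gene Hspb1 read 0.75 ± 0.16. Of 22 oxidative stress genes, 0 rose and 0 fell over all genes (7 at unadjusted p under 0.05), and 3 rose and 0 fell adjusted over the list alone. Their median was 0.28 (camera adjusted p = 1.03e-05, or adjusted p = 0.177 with an estimated correlation). Srxn1 read 0.90 ± 0.14. Of 38 cell cycle genes, 0 rose and 0 fell over all genes (2 at unadjusted p under 0.05), and 0 rose and 0 fell adjusted over the list alone. Their median was -0.42 (camera adjusted p = 2.65e-06, or adjusted p = 0.972 with an estimated correlation). The count was 1 without untreated replicate 1 or either array of doxorubicin day 6, and 0 by limma without untreated replicate 2 (711 at unadjusted p under 0.05), doxorubicin day 1 replicate 1 (544) or 2 (639) or either array of etoposide day 6 (684).

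At day 6 after doxorubicin, Alas2 fell in lung by a log2 change of -6.30 ± 0.49 (limma adjusted p = 0.0064), Hba-a1 of -5.26 ± 0.37, Hbb-bs of -6.07 ± 0.59, Hbb-bt of -6.14 ± 0.59 and Hbb-b2 of -6.11 ± 0.68. The B cell receptor gene Cd22 (-1.31 ± 0.15; other probes -0.70), Rnase6 (-1.70 ± 0.19) and Erich2 (-1.84 ± 0.18) fell, and Kmo of tryptophan breakdown was at least 2.54-fold lower. Cdkn1a rose by 1.58 ± 0.19, Maff, a small Maf transcription factor gene, by 1.65 ± 0.19 and Zfp365 by 1.45 ± 0.18. These were the 12 genes changed (3 higher, 9 lower; 1412 at unadjusted p under 0.05). Of 14 B cell markers, 0 rose and 1 fell over all genes, and 0 rose and 11 fell adjusted over the list alone. Their median was -1.08 (camera adjusted p = 4.59e-13, or adjusted p = 0.0526 with an estimated correlation). Cd79b read -1.02 ± 0.20. Of 10 erythroid genes, 0 rose and 4 fell over all genes, and 1 rose and 6 fell adjusted over the list alone. Their median was -2.65 (camera adjusted p = 7.17e-09, or adjusted p = 0.0526 with an estimated correlation). Of 17 glucocorticoid targets, 0 rose and 0 fell over all genes (10 at unadjusted p under 0.05), and 7 rose and 0 fell adjusted over the list alone. Their median was 0.73 (camera adjusted p = 5.44e-09, or adjusted p = 0.239 with an estimated correlation). Lpin1 read 1.31 ± 0.18. Of the p53 targets, 1 rose and 0 fell over all genes, and 5 rose and 0 fell adjusted over the list alone. Their median was 0.34 (camera adjusted p = 1.88e-05, or adjusted p = 0.0526 with an estimated correlation). The count was 44 without untreated replicate 1, 0 by limma without untreated replicate 2 (1318 at unadjusted p under 0.05), 5 and 6 without doxorubicin day 6 replicates 1 and 2 and 4 without either array of etoposide day 6. Without background correction 9 genes were higher and 8 lower.

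After etoposide no lung gene passed the test in limma at day 1 (0 of 12135, 930 at unadjusted p under 0.05) or day 6 (0, 1115 at unadjusted p under 0.05). Camera with the preset correlation called 16 lists at day 1 and 10 at day 6, against 0 on both days with an estimated one, and fry called 0 and 3. At day 1, of the heat shock genes, 0 rose and 0 fell over all genes (7 at unadjusted p under 0.05), and 5 rose and 0 fell adjusted over the list alone. Their median was 0.40 (camera adjusted p = 2.63e-06, or adjusted p = 0.403 with an estimated correlation). Hspb1 read 0.63 ± 0.16. Of the B cell markers, 0 rose and 0 fell over all genes (4 at unadjusted p under 0.05), and 0 rose and 3 fell adjusted over the list alone. Their median was -0.45 (camera adjusted p = 1.27e-04, or adjusted p = 0.403 with an estimated correlation). The IgE receptor gene Fcer2a read -0.74 ± 0.13. Hepatocyte genes had a median of 2.44 (camera adjusted p = 1.48e-06, or adjusted p = 0.644 with an estimated correlation), and their mean was 8.88 in replicate 2 and 5.98 in replicate 1. At day 6, of the B cell markers, 0 rose and 0 fell over all genes (8 at unadjusted p under 0.05), and 0 rose and 8 fell adjusted over the list alone. Their median was -0.77 (camera adjusted p = 1.84e-10, or adjusted p = 0.131 with an estimated correlation). Cd22 read -1.29 ± 0.15 and the kinase gene Blk at -1.28 ± 0.25. Of the heat shock genes, 0 rose and 0 fell over all genes (9 at unadjusted p under 0.05), and 9 rose and 0 fell adjusted over the list alone. Their median was 0.53 (camera adjusted p = 1.84e-10, or adjusted p = 0.131 with an estimated correlation). Hspa1a read 3.10 ± 0.37 (other probes 1.29) and its co-chaperone gene Dnajb1 at 0.96 ± 0.13. Of the glucocorticoid targets, 0 rose and 0 fell over all genes (8 at unadjusted p under 0.05), and 6 rose and 0 fell adjusted over the list alone. Their median was 0.70 (camera adjusted p = 2.89e-10, or adjusted p = 0.194 with an estimated correlation). Angptl4 read 1.78 ± 0.35. Of 20 neutrophil genes, 0 rose and 0 fell over all genes (8 at unadjusted p under 0.05), and 4 rose and 0 fell adjusted over the list alone. Their median was 1.23 (camera adjusted p = 5.40e-07, or adjusted p = 0.684 with an estimated correlation). Il1r2, a decoy receptor gene of interleukin 1, read 2.59 ± 0.41 and Retnlg at 2.63 ± 0.74. The day 1 count was 1 without untreated replicate 1 and 268 without etoposide day 1 replicate 1, the other array of that group being the one with hepatocyte transcripts. The day 6 count was 1 without etoposide day 6 replicate 1 and 1 without either array of doxorubicin day 1.

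Between the drugs, lung differed in 0 genes at day 1 by limma (961 at unadjusted p under 0.05), while of the p53 targets, 0 rose and 0 fell over all genes (18 at unadjusted p under 0.05), and 16 rose and 0 fell adjusted over the list alone. Their median was 0.45 (camera adjusted p = 3.67e-14, or adjusted p = 0.0087 with an estimated correlation). Cdkn1a read 1.79 ± 0.19 and Phlda3 at 1.33 ± 0.18. At day 6, 7 genes were lower after doxorubicin (563 at unadjusted p under 0.05), among them Alas2 (-6.91 ± 0.49), Hba-a1 (-5.40 ± 0.37), Hbb-b2 (-6.16 ± 0.68), Hbb-bs (-5.90 ± 0.59) and Hbb-bt (-6.03 ± 0.59), and with median centring 2 of 11 were higher. The drug count at day 1 was 1 without either array of doxorubicin day 6 and 300 without etoposide day 1 replicate 1. At day 6 it was 13 without either array of doxorubicin day 1, 4 without etoposide day 6 replicate 1 and 0 by limma without replicate 2 (458 at unadjusted p under 0.05). Without background correction 1 gene was higher and 8 lower at day 6.

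From day 1 to day 6 of doxorubicin, the glucocorticoid targets Fkbp5 (1.94 ± 0.19; limma adjusted p = 0.0165) and Zbtb16 (3.11 ± 0.38) and the semaphorin receptor gene Plxna2 (1.59 ± 0.18) rose in lung. Alas2 (-5.22 ± 0.49), Hba-a1 (-5.48 ± 0.37), Hbb-bs (-5.91 ± 0.59) and Hbb-bt (-6.05 ± 0.59) fell, and the macrophage transcription factor gene Spic was at least 2.15-fold lower. These were the 8 genes that differed (1283 at unadjusted p under 0.05), and with median centring 16.7% rather than 37.5% were higher. Of the B cell markers, 0 rose and 0 fell over all genes (11 at unadjusted p under 0.05), and 0 rose and 11 fell adjusted over the list alone. Their median was -1.07 (camera adjusted p = 3.58e-14, or adjusted p = 0.0805 with an estimated correlation). For etoposide 0 genes differed between the days in limma (1494 at unadjusted p under 0.05), with Zbtb16 at 2.87 ± 0.38 and Il1r2 at 2.87 ± 0.41. The doxorubicin count was 4 and 3 without doxorubicin day 1 replicates 1 and 2, 5 and 4 without doxorubicin day 6 replicates 1 and 2 and 1 without either array of etoposide day 6. The etoposide count was 2 without either array of doxorubicin day 1, 421 without etoposide day 1 replicate 1 and 1 without etoposide day 6 replicate 1. With the authors' deposited values 2 genes were higher and 8 lower at day 6 of doxorubicin, against 3 and 5.

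**Figure D3:**
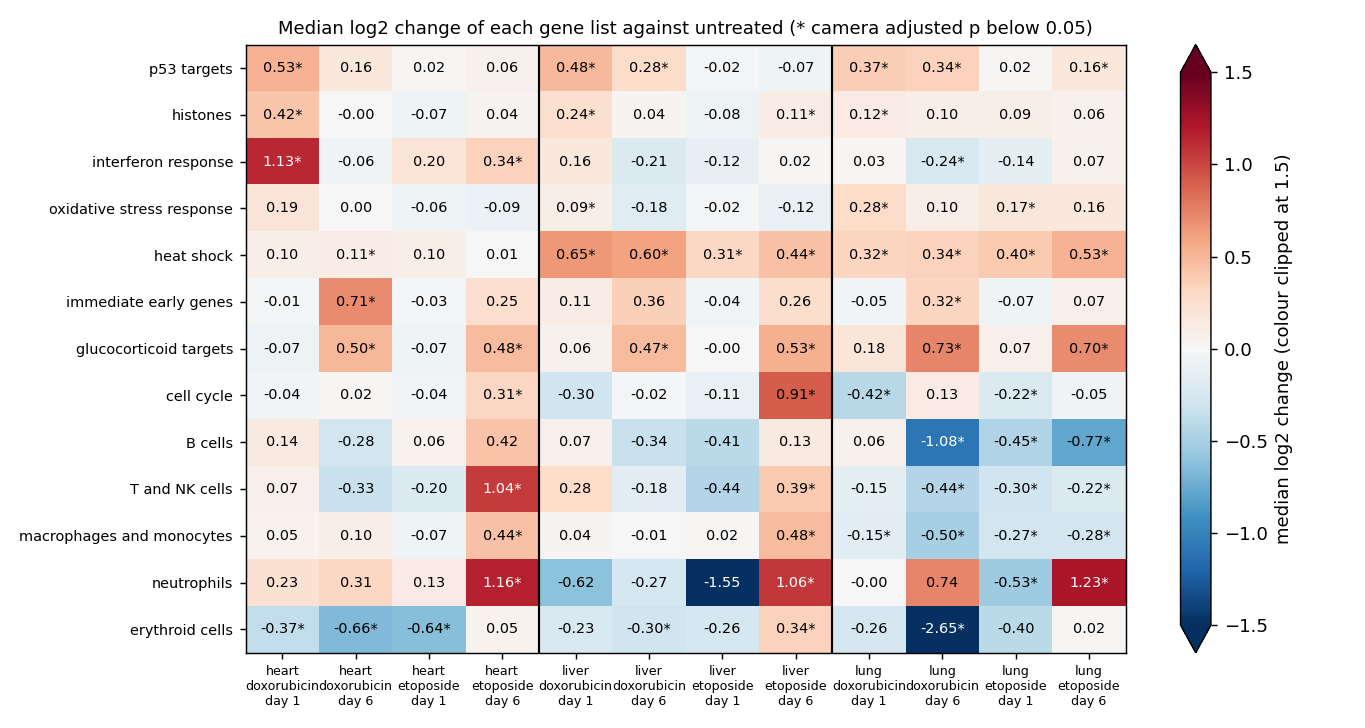
Median log2 change against untreated of 13 gene lists (vertical) in each tissue, drug and day (horizontal), coloured from blue for lower to red for higher, with a star where the camera adjusted p is below 0.05 with the preset correlation. The p53 targets stand at 0.53 in heart, 0.48 in liver and 0.37 in lung at doxorubicin day 1.

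Whether a change differed between tissues was tested as an interaction over all 30 arrays and 13133 genes. The test takes the arrays as independent, although tissues of a treatment may have come from the same mice, which the labels do not pair. At day 1 of doxorubicin, Ifit3 changed by 2.55 in heart, -0.14 in liver and 0.15 in lung, Usp18 by 2.11 in heart, -0.45 in liver and -0.15 in lung, Srxn1 by 2.34 in heart, 0.47 in liver and 0.96 in lung and Hsp90aa1 by -0.14 in heart, 1.87 in liver and 0.42 in lung, among 909 genes whose change differed by limma (2728 at unadjusted p under 0.05). The change of the interferon-stimulated genes was higher in heart than in lung (camera adjusted p = 2.88e-11, or adjusted p = 0.515 with an estimated correlation) and than in liver (camera adjusted p = 0.0026, or adjusted p = 0.99 with an estimated correlation). At day 6 of doxorubicin 128 genes differed (1993 at unadjusted p under 0.05), with Atf3 at 3.26, 0.56 and 0.06 and Irs2 at 2.34, -0.87 and 0.63 in heart, liver and lung. The change of the B cell markers was lower in lung than in liver (camera adjusted p = 5.86e-06, or adjusted p = 0.104 with an estimated correlation). In untreated mice 13 of the 14 B cell markers were above background on both arrays in lung, 10 in liver and 3 in heart, where too few were measured to show a fall, so lung is not set against heart. For etoposide 27 genes differed at day 1 (1514 at unadjusted p under 0.05) and 55 at day 6 (1789), the latter including Vldlr (0.16, -2.24 and -0.25 in heart, liver and lung) and Irs2 (1.89, -0.76 and 0.71). At day 6 of etoposide the change of the B cell markers was lower in lung than in liver (camera adjusted p = 5.20e-08, or adjusted p = 0.0391 with an estimated correlation), and that of the cell cycle list higher in liver than in lung (camera adjusted p = 1.25e-13, or adjusted p = 0.645 with an estimated correlation). Of the 909 genes 260 were read by the 852 probes, and 535 genes differed without these.

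Single arrays moved the number of genes whose change differed between tissues. For doxorubicin day 1 it was 493 without heart doxorubicin day 1 array 1, 543 without liver untreated array 2 and 431 without liver doxorubicin day 1 array 2. For doxorubicin day 6 it was 75 without lung untreated array 2, 55 without lung doxorubicin day 6 array 1, 58 without lung doxorubicin day 6 array 2, 226 without heart untreated array 2, 201 without heart doxorubicin day 6 array 2, 42 without liver untreated array 1, 80 without liver untreated array 2 and 34 without liver doxorubicin day 6 array 2. For etoposide day 1 it was 14 without lung untreated array 1, 13 without lung untreated array 2, 234 without lung etoposide day 1 array 1, 9 without lung etoposide day 1 array 2, 9 without heart etoposide day 1 array 2, 10 without liver untreated array 1, 17 without liver untreated array 2, 8 without liver etoposide day 1 array 1 and 6 without liver etoposide day 1 array 2. For etoposide day 6 it was 23 without lung untreated array 1, 20 without lung etoposide day 6 array 1, 23 without lung etoposide day 6 array 2, 694 without heart etoposide day 6 array 1, 91 without heart etoposide day 6 array 2, 0 by limma without liver untreated array 1, 36 without liver untreated array 2, 30 without liver etoposide day 6 array 1 and 6 without liver etoposide day 6 array 2.

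In liver the changes after doxorubicin and etoposide ran together across genes, which are not independent replicates. Their correlation was 0.806 at day 1 and 0.697 at day 6, against 0.50 for simulated unchanged groups set against the same untreated arrays (mean of 100), and the covariance exceeded the simulated 0.0222 by 0.132 and 0.114. Of the liver genes, 435 were higher after both drugs at day 1 (31 for independent lists) and 28 lower after both (1.48), with 112 (5.83) and 65 (1.99) at day 6. Both lists rest on the same untreated arrays, which were low on the 852 probes, and the numbers for independent lists leave this out. Without those probes 145 genes were higher after both (5.47 for independent lists) and 7 lower (0.352) at day 1, with 27 (0.586) and 22 (0.409) at day 6, and the correlations were 0.724 and 0.646. With 1 untreated array for each drug the correlation was 0.467 or 0.550 at day 1 and 0.630 or 0.265 at day 6, by which array went to which drug. As either array was low on the set and other probes followed it, a shared response is not told apart from the array difference. In heart the correlations were 0.398 at day 1 and 0.547 at day 6 against a simulated 0.502, with covariance differences of -0.0036 and 0.0222, and in lung 0.454 and 0.637 against 0.497, with differences of 0.0111 and 0.0398.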

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

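The tests on the probe set (other probes, heart), on blood, atrial share and shared globin probes, and on the array difference and immune cells behind the interferon genes were chosen only after the result was seen. By an interaction test the change differed between tissues in 909 and 128 genes at days 1 and 6 of doxorubicin and in 27 and 55 genes for etoposide. Between day 6 and day 1 of the same drug, 35 heart genes and 48 liver genes differed for doxorubicin, 51 liver genes for etoposide and 8 lung genes for doxorubicin.

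The 909 genes include 260 read by the probe set that was higher in treated than in untreated liver, where 98.8% of its 732 detected probes rose at doxorubicin day 1 with a median of 1.23. Where the same genes had other detected probes, these had a median change of -0.0372 (SE 0.0209, 531 probes) against 1.16 for the set's own. Probes of the same gene thus disagreed. The other probes are those that missed the cut in the heart pair that chose the set, so a low value is partly built in. Genes with all detected probes in the set are left out, and the comparison does not by itself decide on a change in transcript level. The set's median rise stayed at 0.850 or above with no background correction, median centring and the authors' values, which argues against the normalization. In heart under the same drug and day the set's median was -1.16 (SE 0.023), the opposite direction, as a difference between arrays apart from treatment could give. Its source, such as labelling or hybridization, is not given in the sources used here, and part of the liver counts may stem from it.

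Globin transcripts were lower at day 6 after doxorubicin in all 3 tissues. Less blood in the tissue as the whole cause is argued against in liver and lung by neutrophil genes that stood at least 1 (log2) above the floor in the untreated arrays, whose medians were 0.0287 (SE 0.172, 9 genes) and 0.735 (SE 0.327, 18 genes). In heart 3 such genes were left (median 1.45), too few to decide. Probes shared between globin copies would leave Alas2 in place, yet its smaller change over heart and lung was -4.74 or lower, a bound, as in heart its probe was not above background after treatment. Other normalizations left a change of Hba-a1 of -5.18 or lower in each tissue. Fewer young red cells in the circulation may account for the pattern in liver and lung, a hypothesis found on the same data and not tested further. A larger atrial share of the heart samples as the whole cause is argued against by a change of Hba-a1 of -6.79 or lower (SE 0.425) against untreated replicate 2 alone and etoposide day 6 replicate 2 alone, which were also high in atrial genes. Less blood stays open in all 3 tissues.

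Interferon-stimulated genes were higher in heart at day 1 after doxorubicin, with a median of 1.13. The array difference behind the probe set would lower them in liver (median 0.16, SE 0.126), but it is not excluded for single genes. Correlations with the set's deviation in heart and liver were -0.75 and -0.69 for Usp18 and -0.78 and -0.68 for Isg15. For Ifit3 they were -0.75 and -0.32 and for Mx2 -0.65 and 0.01. More macrophages would raise their markers, whose median was 0.0482 (SE 0.145, 24 genes above background). For T and natural killer cells 7 markers above background (median 0.242, SE 0.227) leave this open. Without the untreated array with airway transcripts the list's median was 1.41, and without the other 0.72. An interferon response of heart cells to doxorubicin may account for the pattern, which rests on 2 treated arrays and lost its call with an estimated correlation (adjusted p = 0.235).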

How the results depend on the processing

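The probe set (in the counts and in the agreement of the drugs), its covariate and its correlation with single genes, the omission of the arrays with airway transcripts and the exchanged lung numbers were tests chosen after the results were seen. Over the called genes chosen by the rule and all alternatives, 2940 values kept direction and side of the threshold, 1138 kept direction only and 14 changed direction, all 14 with the deviation of the probe set as a covariate. Of the called gene lists, 246 values kept their call, 396 lost it and 0 changed direction. With 2 arrays per group, signal over background limits dim probes to bounds on the fold. A slide block was not run, as no slide is given in the sources used here. Counts in brackets beside a 0 from limma are at unadjusted p under 0.05, and the cause of the changes was not tested where none is given.

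Without background correction the counts that moved by over 1.5 times were in heart 8 for doxorubicin day 1, 1 for the drugs at day 1, in liver 5 for the drugs at day 1, 89 for the days of etoposide and in lung 5 for doxorubicin day 1. With the authors' deposited values they were in heart 1 for doxorubicin day 1, 0 (434) for etoposide day 1, 0 (700) for etoposide day 6, 1 for the drugs at day 1, in liver 89 for etoposide day 6, 0 (837) for the drugs at day 1, 17 for the days of doxorubicin, 26 for the days of etoposide and in lung 1 for doxorubicin day 1, 4 for the drugs at day 6. There the number of genes whose change differed between tissues was 13 for etoposide day 1, 8 for etoposide day 6. With no filter on dim probes, which adds genes to the test, they were in heart 5 for doxorubicin day 1, in liver 14 for etoposide day 6, 0 (1417) for the drugs at day 1, 20 for the days of doxorubicin, 19 for the days of etoposide and in lung 5 for doxorubicin day 6, 1 for the days of doxorubicin. There the number of genes whose change differed between tissues was 33 for etoposide day 6. With probes detected on every array, which leaves fewer genes in the test, they were in heart 17 for doxorubicin day 1, 0 (273) for etoposide day 1, 0 (531) for etoposide day 6, 1 for the drugs at day 1, 3 for the drugs at day 6, 77 for the days of doxorubicin, in liver 330 for etoposide day 6, 2 for the drugs at day 6, 74 for the days of doxorubicin and in lung 3 for the drugs at day 6. There the number of genes whose change differed between tissues was 63 for doxorubicin day 6, 3 for etoposide day 1. With the mean of a gene's probes they were in heart 7 for doxorubicin day 1 and in lung 2 for the drugs at day 1. There the number of genes whose change differed between tissues was 83 for etoposide day 6.

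With median centring they were in liver 153 for the days of etoposide and in lung 11 for the drugs at day 6. There the number of genes whose change differed between tissues was 30 for etoposide day 6. With a variance trend they were in heart 8 for doxorubicin day 1, in liver 416 for etoposide day 6, 5 for the drugs at day 1, 155 for the days of etoposide and in lung 5 for doxorubicin day 1, 20 for doxorubicin day 6, 2 for the drugs at day 1. With 1 fit over all 30 arrays, which estimates the spread from more groups, they were in heart 588 and 60 for doxorubicin days 1 and 6. There they were 0 (666) and 7 for etoposide, 374 and 21 for the drugs and 1047 and 38 for the days of doxorubicin and etoposide. In liver they were 337 for etoposide day 6, 58 and 14 for the drugs and 273 and 325 for the days. In lung they were 25 and 145 for doxorubicin, 52 for etoposide day 6, 16 and 31 for the drugs and 87 and 127 for the days. With median centring Top2a differed between lung and liver by 1.64 (adjusted p = 0.0219), now past the threshold, and Top2b between lung and heart by 0.0871 (adjusted p = 0.863), with the sign reversed. The larger share of the calls changed sides (higher and lower genes) without background correction in lung for doxorubicin day 6 (9 and 8). It did so with probes detected on every array in heart for doxorubicin day 6 (5 and 3), in lung for the days of doxorubicin (4 and 3). It did so with the replicate block in liver for the days of etoposide (117 and 92). It did so with 1 fit over all 30 arrays in heart for doxorubicin day 1 (257 and 331), doxorubicin day 6 (40 and 20), etoposide day 6 (6 and 1), the drugs at day 1 (118 and 256), the drugs at day 6 (13 and 8), the days of doxorubicin (603 and 444), in liver for etoposide day 6 (146 and 191), the days of etoposide (181 and 144), in lung for doxorubicin day 6 (99 and 46), the days of doxorubicin (45 and 42). It did so with the deviation of the probe set as a covariate in heart for doxorubicin day 1 (0 and 1), in liver for doxorubicin day 6 (0 and 3). It did so without the arrays with airway transcripts in heart for doxorubicin day 6 (42 and 12), the days of doxorubicin (321 and 98).

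Pairing by replicate number stays open: deviations of same-numbered arrays correlated by -0.34 to 0.60 in heart, -0.28 to 0.37 in liver and -0.20 to 0.30 in lung, above 0.1 in 7, 6 and 3 of 10 pairs. With the number as a replicate block the counts that moved by over 1.5 times were in heart 8 for the days of doxorubicin, in liver 340 for etoposide day 6, 0 (992) for the drugs at day 1, 209 for the days of etoposide and in lung 0 (761) for doxorubicin day 1. With the numbers of etoposide day 1 exchanged in the block, the lung count for the days of etoposide was 27. With the block 2 gene lists were called in liver at etoposide day 1, against 1 without it.

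Dropping the probe set left in other probes that followed it. Liver counts were then 501 and 361 for doxorubicin days 1 and 6 and 204 and 56 for etoposide. Of these, 500, 360, 204 and 56 genes were shared with the full set of probes. Between tissues 535 genes then differed at doxorubicin day 1. With the deviation of the set as a covariate, which nearly coincides with treatment in liver, the counts were in heart 1 for doxorubicin day 1, 0 (513) for the drugs at day 1, 1 for the days of doxorubicin and in liver 0 (609) for doxorubicin day 1, 3 for doxorubicin day 6, 0 (605) for etoposide day 1, 0 (587) for etoposide day 6, 0 (1052) for the drugs at day 1, 15 for the days of doxorubicin, 0 (1634) for the days of etoposide. Without the heart arrays with airway transcripts they were in heart 54 for doxorubicin day 6, 0 (1774) for the drugs at day 1, 2 for the drugs at day 6, 419 for the days of doxorubicin. Without the set the correlation of the drugs' changes was 0.470 in heart day 1 and 0.724 and 0.646 in liver days 1 and 6.

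Within tissues, camera with an estimated correlation called 1 list in each of liver for the drugs at day 6, lung for doxorubicin day 1 and lung for the drugs at day 1, and 0 in each other contrast. The rotation test fry, which does not compare a list with other genes, called 4 lists at doxorubicin day 1 in each of heart and liver, within 1.5 times of camera's 6 and 4. Elsewhere it called in heart 1 for doxorubicin day 6, 4 and 1 for the drugs at days 1 and 6 and 4 for the days of doxorubicin. In liver it called 2 for doxorubicin day 6 and 1 each for the drugs at day 6 and the days of either drug. In lung it called 1 and 5 for doxorubicin days 1 and 6, 3 for etoposide day 6, 1 for the drugs on each day and 5 for the days of doxorubicin. In each other contrast it called 0. With 1 untreated array for each drug, the correlation of the drugs' changes at days 1 and 6 was -0.152 and 0.0949 in heart, 0.467 and 0.63 in liver and -0.0855 and 0.227 in lung. With the other assignment it was 0.0525 and 0.0272 in heart, 0.55 and 0.265 in liver and 0.0231 and 0.104 in lung.

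Leaving out each array in turn gave counts in heart 2 to 205 for doxorubicin day 1, 4 to 8 for doxorubicin day 6, 1 to 2 for etoposide day 6, 0 to 113 for the drugs at day 1, 2 to 7 for the drugs at day 6, 2 to 332 for the days of doxorubicin, in liver 112 to 927 for doxorubicin day 1, 72 to 737 for doxorubicin day 6, 123 to 606 for etoposide day 1, 0 to 403 for etoposide day 6, 0 to 6 for the drugs at day 1, 4 to 25 for the drugs at day 6, 4 to 33 for the days of doxorubicin, 0 to 163 for the days of etoposide and in lung 0 to 3 for doxorubicin day 1, 0 to 44 for doxorubicin day 6, 0 to 268 for etoposide day 1, 0 to 1 for etoposide day 6, 0 to 300 for the drugs at day 1, 0 to 13 for the drugs at day 6, 1 to 11 for the days of doxorubicin, 0 to 421 for the days of etoposide. No range beyond the value itself was seen for the heart counts for etoposide day 1 (1) and the days of etoposide (0 by limma, 840 at unadjusted p under 0.05). The number of genes whose change differed between tissues ran over 431 to 956 for doxorubicin day 1, 34 to 226 for doxorubicin day 6, 6 to 234 for etoposide day 1, 0 to 694 for etoposide day 6. Of the called genes chosen by the rule, 15 to 33 of 36 kept their call in heart, 74 to 120 of 135 in liver and 5 to 21 of 28 in lung. In lung the call of Cdkn1a was kept on leaving out 0 of 10 arrays at doxorubicin day 1 and 1 of 10 at doxorubicin day 6, and in heart at doxorubicin day 6 the calls of Alas2 and Irs2 were kept on leaving out 2 of 10. Of the 148 called changes printed in the report, 36 kept their call on leaving out each of the 10 arrays, 34 kept it on 3 or fewer of them and 0 changed direction. In liver 3 values moved by over 1.5 times: Cdkn1a and Chac1 at doxorubicin day 1 and Sult2a6 at etoposide day 1.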

Other observations

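The gene lists below were fixed before the results were seen, and Ces1c was looked at by array afterwards. Glucocorticoid targets, induced by corticosterone, had a median of 0.50 in heart at doxorubicin day 6 (camera adjusted p = 0.0022, or adjusted p = 0.431 with an estimated correlation) and of 0.48 at etoposide day 6 (camera adjusted p = 1.50e-04, or adjusted p = 0.701 with an estimated correlation). In those contrasts 0 rose and 0 fell over all genes (6 and 8 at unadjusted p under 0.05) and adjusted over the list alone. In liver, acute phase genes, secreted by hepatocytes in inflammation, had a median of 0.42 at doxorubicin day 6 (camera adjusted p = 0.0212, or adjusted p = 0.995 with an estimated correlation) and of 0.53 at etoposide day 6 (camera adjusted p = 7.15e-04, or adjusted p = 0.9 with an estimated correlation). In lung at etoposide day 6, genes of the extracellular matrix and fibroblasts had a median of -0.33, and 0 rose and 0 fell over all genes (9 at unadjusted p under 0.05), and 0 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.81e-04, or adjusted p = 0.813 with an estimated correlation). Alveolar genes were lower after doxorubicin than after etoposide at day 1 in lung (median -0.39; camera adjusted p = 4.62e-09, or adjusted p = 0.304 with an estimated correlation), where 0 rose and 0 fell over all genes (9 at unadjusted p under 0.05), and 0 rose and 5 fell adjusted over the list alone.

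Ces1c, a carboxylesterase gene, read 8.58 and 8.60 (log2) in the untreated heart arrays and 4.38 to 4.80 in the 8 treated ones. In liver it read 13.1 in replicate 2 of doxorubicin day 1 and 13.5 in replicate 1 of etoposide day 1, and 6.20 to 7.34 in the other 8 arrays. In lung it read 7.20 in replicate 2 of etoposide day 1, the array with hepatocyte transcripts, and 4.38 to 4.73 in the others.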
